A study of Homo sapiens with 4 samples.

How the data were processed

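Peripheral blood mononuclear cells from HFpEF and control conditions had been thawed, stained with TotalSeq antibodies and profiled with 10x Genomics 5′ chemistry, with 1 gene expression library and 1 antibody library per condition. The deposited matrices hold whole-number UMI counts per gene or antibody and cell, made by the authors with Cell Ranger 6.1.1 (per the file headers) on GRCh38, with Seurat also named in the submitters' processing notes. The other columns of the deposited files, per the file headers and values, hold the names and kinds of the features and the cell barcodes, and carry no measurement. Each matrix covers 36601 genes and 142 antibody features, which are 137 panel antibodies (7 of them isotype controls) and 5 hashtags. Panel antibodies were named by their full identifiers, since the deposited short names of the CD8 and CD22 antibodies did not match these. The identifiers were not checked against a panel sheet. The lowest gene UMI total of a barcode was 500 in both libraries, and the filter behind this is not given in the sources used here. Which matrix belongs to which condition was taken from its name.

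Cells with at least 500 UMIs, at least 250 genes and under 10% mitochondrial UMIs were kept, which left 20036 control and 18603 HFpEF cells. The mitochondrial limit removed 13.2% and 17.7% of barcodes. Doublets were called in each library with scrublet as implemented in scanpy 1.11.5 (expected rate 0.1, thresholds 0.256 and 0.253) and removed, 2113 control (10.5%) and 2265 HFpEF cells (12.2%). Kept cells had a median of 1162 and 1160 genes. Both libraries were clustered together after scaling to 10000 UMIs per cell and log1p, with 2000 variable genes chosen within each library, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1. XIST, Y-linked, immunoglobulin, T cell receptor, mitochondrial and ribosomal protein genes were left out of the clustering. Clusters were named by fixed markers among their 20 leading genes (at least 2 markers, prior of 10 CPM), and a cluster with platelet markers and under 10000 CPM of PPBP was named as mixed, with its next highest marker score as partner. A cluster with fewer markers took the name of its highest marker score. This applied to the classical monocyte cluster led by G0S2 and IL1B. Monocytes are the classical and nonclassical monocyte-like clusters together.

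Each group is 1 sample, so there was no test and no p-value, and all comparisons are HFpEF against control. Class shares have exact binomial (Clopper-Pearson) 95% intervals and their differences Wald 95% intervals. UMIs were summed per class and library and scaled to CPM of the class total, and ratios have exact conditional binomial 95% intervals. All intervals cover counting error only. A gene was compared in a class with at least 200 UMIs over both libraries and at least 20 CPM in 1 of them, and a library with 0 counts was set to 3. Totals ran from 3340921 UMIs (HFpEF B cells) to 21409063 (control CD4 T cells). Tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3. Positions are from the GENCODE annotation of GRCh38, in which all 73 named genes looked up were found.

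The design, the 25 gene lists, each in its own classes (65 pairs), and the rule for named genes were fixed before the data were examined. The rule takes the 10 highest and 10 lowest genes in monocytes and CD4 T cells, and 5 and 5 in the other classes, by the bound of the interval nearest to 1 among genes at least 1.5-fold apart. It leaves out XIST and Y-linked genes, mitochondrial, ribosomal, immunoglobulin, T cell receptor, HLA, KIR, haemoglobin, platelet and erythroid genes, a fixed set of genes with common deletions or strong donor variants (which did not hold KLRC2 or KANSL1-AS1), and genes of which 5 cells held over 20% of a library's UMIs. A list's median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of expression, and needed at least 3 measured members. Lists with fewer members, or present to show other cells, are given as summed CPM.

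Hashtags were called in each library by a mixture of 2 normal components on centred log counts. In control, 14450 cells carried 1 hashtag, 3444 several (19.2%) and 29 none, and in HFpEF 12924, 3292 (20.1%) and 122. The use of the sets as sub-samples was chosen after the data were seen. Antibody counts were summed per class and divided by all antibody counts of those cells. The minimum for antibodies (a mean of at least 1 count per cell in 1 library, at most 20% in 5 cells), the 1.5-fold limit and the naming of the 3 highest and 3 lowest without isotype controls, plus platelet antibodies, were also chosen after the data were seen.

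Alternatives fixed beforehand were stricter and looser cell filters (1000 UMIs and 5%, or 200 genes and 20% mitochondrial UMIs), doublets kept, resolutions of 0.5 and 2, separate clustering, antibody gates, TMM and median-of-ratios factors, a minimum of 50 UMIs without a CPM filter, no filter, the mean of per-cell CPM, thinning to 1000 UMIs per cell, and centred log ratios for antibodies. Thinning left out cells below that depth, up to 12.6% of a class (HFpEF monocytes). Alternatives added after the data were seen were removal of cells with several hashtags, the median over hashtag sets, leaving out each set in turn, single clusters of a class, hashtags left out of the antibody total, and leaving out the 1% of cells with the most antibody counts. The procedure was tested on simulated data in which 100 genes of each class differed 2.5-fold and 100 differed 1.2-fold. It found 97, 98, 96, 89 and 82 of the former at 2-fold in monocytes, CD4 T, CD8 T, NK and B cells, 0 of the latter and 0 unchanged genes, and intervals held the true ratio for 95.1 to 95.5% of genes. Of 200 random lists, 5 or 6 per class fell outside the central 95%. The simulated libraries held counting noise only. These values therefore do not show how often differences between sub-samples or libraries pass the same limits.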

Results

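Peripheral blood mononuclear cells of a group with heart failure with preserved ejection fraction (HFpEF) and of a control group were profiled by CITE-seq, in which the RNA and antibody tags bound to surface proteins are counted in the same cells. The comparison asks how circulating immune cells differ between the conditions. There was 1 gene expression library and 1 antibody library for each condition, and both come from the same cells, so each group is 1 sample and no test between groups was possible. Every interval given covers counting error only. The control library held 23092 barcodes with 73839326 gene UMIs (unique molecular identifiers, each counting 1 captured RNA molecule), and the HFpEF library 22627 barcodes with 64509487. After removal of low-quality cells and called doublets, 17923 control cells with a median of 2941 UMIs and 16338 HFpEF cells with a median of 2721 UMIs remained. The antibody libraries held 27134444 and 26754153 counts.

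Each library also carried 5 hashtag antibodies, a kind of tag generally used to mark sub-samples before they are combined. What each hashtag marks is not given in the sources used here. The 5 hashtag sets of a library were therefore treated as unmapped sub-samples, and their lowest and highest values are given beside a value where they help to read it. The ranges of 5 control and 5 HFpEF sets lie apart in 2 of the 252 ways of splitting 10 sets. This is 0.794% by chance for exchangeable sets. Sets of a condition share 1 library, so a difference between libraries also sets ranges apart and cannot be told from the condition. Such ranges were apart for 135 of 5895 genes in monocytes (2.29%), 81 of 4996 in CD4 T cells (1.62%), 93 of 5653 in CD8 T cells (1.65%), 96 of 5475 in NK cells (1.75%) and 51 of 4007 in B cells (1.27%).

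The HFpEF library held fewer CD4 T-like cells and more classical monocyte-like and CD8 T-like cells than the control library. CD4 T-like cells, which include a cluster led by FOXP3, were 33.7% of control cells (exact 95% binomial interval 33.1 to 34.4) and 18.3% of HFpEF cells (17.7 to 18.9). Classical monocyte-like cells were 28.3% of control cells (27.6 to 29) and 37.8% of HFpEF cells (37.1 to 38.6), and CD8 T-like cells were 10.1% (9.70 to 10.6) and 16.5% (15.9 to 17.0). The CD8 T-like cells fell into a naive-like cluster led by LINC02446, CD8B and NELL2, with 4.27% of control and 1.96% of HFpEF cells, and a cluster led by CD8A, GZMH and CCL5, with 5.86% and 14.5%. NK-like cells were 10.5% and 8.48%, B-like cells 7.25% and 7.01%, and nonclassical monocyte-like cells 5.23% and 5.52%. Conventional dendritic-like cells were 2.64% and 1.43%, and plasmacytoid dendritic-like cells 0.519% and 0.722%. Several genes that lead these clusters also differed in the pooled class (NELL2, KLRC2 and ZNF683 in CD8 T cells, and LYPD2, CKB and CCL3 in monocytes), so the sizes of those clusters and the expression of those genes are not separate observations.

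The shares of the hashtag sets overlapped between libraries for the large classes. Control sets ran from 20.3 to 44.4% and HFpEF sets from 12.2 to 33.3% for CD4 T cells, from 14.0 to 36% and 26.6 to 55.8% for classical monocytes, and from 3.75 to 15.1% and 2.79 to 27.8% for CD8 T cells. The difference for classical monocytes (HFpEF minus control) was 9.54 percentage points and was 5.43 without the HFpEF Hashtag4 set. For CD8 T cells it was 6.33 points, 3.95 without HFpEF Hashtag2, 4.12 without HFpEF Hashtag1, and −1.19 when the medians of the sets were compared. For NK cells it was −1.98 points, −0.532 without control Hashtag5, −0.973 without HFpEF Hashtag2, −3.57 without control Hashtag2, −3.12 without HFpEF Hashtag3 and −2.99 without HFpEF Hashtag5. Keeping called doublets made it −0.149, and the medians of the sets −4.12. For plasmacytoid dendritic cells it was 0.203 points, −0.024 without HFpEF Hashtag3 and 0.361 without HFpEF Hashtag4. The differences for B cells (−0.239, counting interval −0.785 to 0.306) and nonclassical monocytes (0.287, −0.191 to 0.766) were not detectable at this depth. With antibody gates in place of clusters, which left 39.9% of control and 45.9% of HFpEF cells outside every gate, the differences were −5.76 points for CD4 T cells, 3.15 for classical monocytes, 0.095 for CD8 T, −0.616 for NK and −2.66 for B cells. The gates held a smaller part of each class in HFpEF, such as 23.1% of control and 15.2% of HFpEF CD8 T-like cells. For B-like cells this was 60.2% and 38.0%. Of NK-gated cells, 52.5% and 31.6% were NK-like. Unequal capture therefore bears on these differences.

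A small group of cells carried both platelet and monocyte RNA and was larger in the HFpEF library. Its leading genes included PPBP, PF4 and TUBB1, which platelets and their precursors express, and its next highest marker score was that of monocytes. It held 81 control cells (0.452%, interval 0.359 to 0.561) and 335 HFpEF cells (2.05%, 1.84 to 2.28). Control sets ran from 0.176 to 0.435% and HFpEF sets from 0.934 to 1.30%, which made it the only class named so far with ranges apart. More than 1 hashtag was called in 56.7% of these cells, so the value of a whole library lies above those of its sets. The difference was 1.60 percentage points, 0.870 without cells that carried several hashtags and 0.705 when each library was clustered on its own. Surface CD41, an integrin chain of platelets, averaged 209 counts per mixed cell in control and 204 in HFpEF, against 33.2 and 38.0 per monocyte. In mixed cells with 1 hashtag the CD41 means were 148 and 114 and the medians 138 and 64.5. PPBP, 1 of the genes that define the group, was also higher in HFpEF in the remaining monocytes. Cells with platelet genes alone were 0.552% and 0.808%, and cells mixing platelet and lymphocyte genes 0.312% and 0.545%. An unnamed cluster led by immunoglobulin genes held 0.257% and 0.728%, and progenitor-like cells 0.145% and 0.129%.

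**Figure D1:**
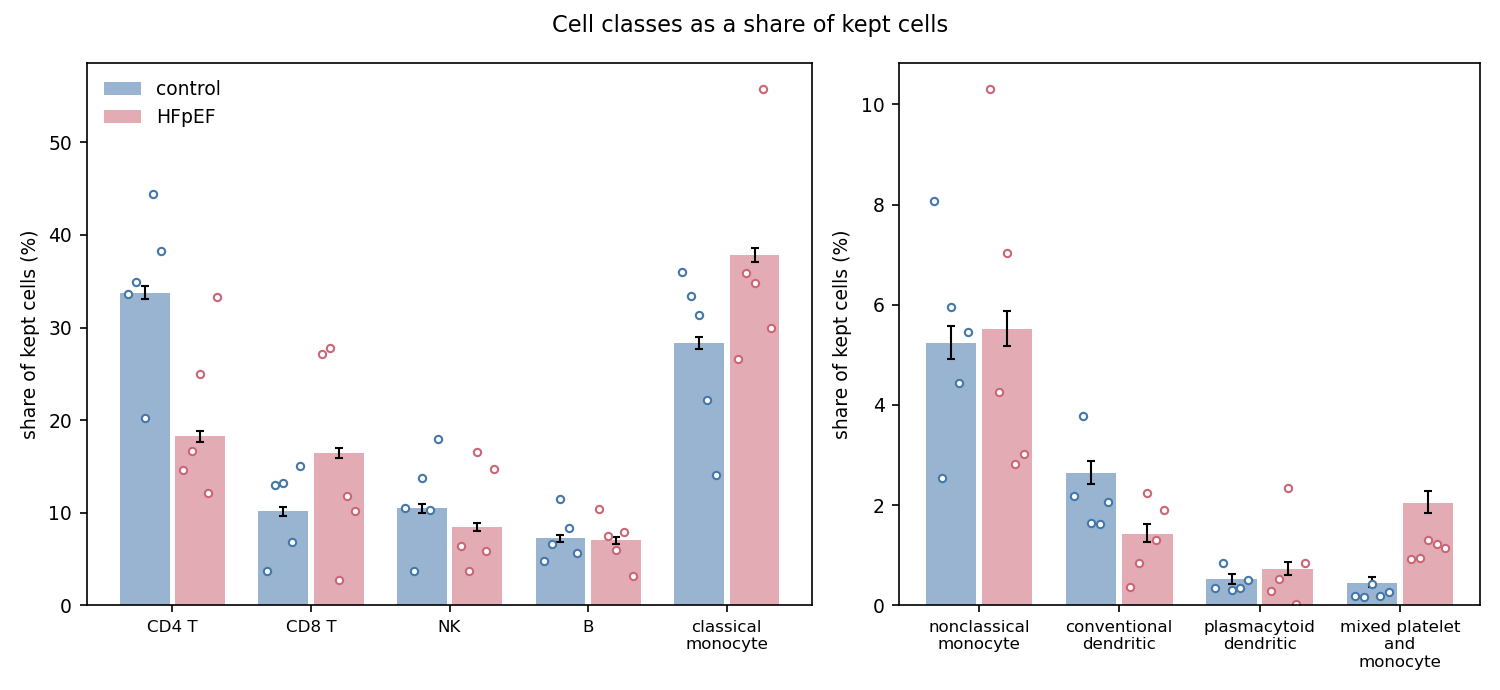
Share of kept cells (percent, vertical axis) in each cell class of the control and the HFpEF library; bars show all cells with exact 95% binomial intervals for counting error, and open points the 5 hashtag sets of each library. CD4 T cells were 33.7% of control and 18.3% of HFpEF cells, and cells mixing platelet and monocyte RNA 0.452% and 2.05%.

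In monocytes, the HFpEF library had higher medians for the lists of classical monocyte genes, of Fc receptors, complement and integrins, and of the interferon response, and lower levels of LYPD2 and CKB, which nonclassical monocytes express. Of 5895 genes with enough counts, 33 were at least 2-fold higher and 16 at least 2-fold lower in HFpEF, which describes these libraries and is not a count from a test. CCR2, the chemokine receptor through which monocytes leave the marrow and enter tissue, stood at 14.6 CPM (the UMIs of a gene scaled to a common class total) in control and 50.7 in HFpEF, a ratio of 3.48 (counting interval 3.02 to 4.03). CLU, which encodes the secreted chaperone clusterin, stood at 6.19 and 41.4 CPM, a ratio of 6.69 (5.44 to 8.29). Both had hashtag ranges apart, with control sets from 5.99 to 26.8 and HFpEF sets from 27 to 78.4 CPM for CCR2, and from 2.84 to 17.2 and 25.5 to 67.2 CPM for CLU. CLU is also abundant in platelets. In the platelet-like cluster it stood at 4619 and 4709 CPM beside 27668 and 42923 CPM of PPBP, whereas in HFpEF monocytes CLU (41.4 CPM) and PPBP (48.2 CPM) were at similar levels. In the GENCODE annotation of GRCh38, CCR2 (ENSG00000121807) lies on chromosome 3 from 46353734 to 46360928 and CLU (ENSG00000120885) on chromosome 8 from 27596917 to 27615031.

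The other genes highest in HFpEF monocytes by the fixed rule were FOLR3 (ratio 8.36), EGR1 (3.21), CCL3 (2.84), EGR2 (3.16), CES1 (2.92), CXCL2 (2.82), RNASE2 (2.70) and SIGLEC1 (2.65). EGR1 and EGR2 are transcription factors induced within minutes of stimulation, and CCL3 and CXCL2 are inflammatory chemokines. Their hashtag ranges overlapped, and the HFpEF Hashtag4 set carried part of the difference: without it the log2 ratio was 2.01 for FOLR3 (3.06 with it), 0.63 for CCL3 and 0.73 for CXCL2 (both 1.5 with it). Without the cluster led by G0S2 and IL1B, that of CCL3 was 0.20. Genes lowest in HFpEF monocytes were LYPD2 (207 and 63.6 CPM, ratio 0.307) and CKB (0.449), both expressed by nonclassical monocytes, THBS1 (52.8 and 15.4 CPM, 0.292), TSPYL2 (0.383), TCF7 (0.391), KANSL1-AS1 (0.403), G0S2 (0.474), U2AF1 (0.458), GRASP (0.451) and CD3E (0.480). Nonclassical monocytes were 15.6% of control and 12.7% of HFpEF monocytes. TSPYL2 had hashtag ranges apart. Without the control Hashtag2 set the log2 ratio was −0.98 for THBS1 (−1.77 with it) and −0.19 for G0S2 (−1.08). CD3E and TCF7 are T cell genes, and their library values lay above those of every set in control (CD3E 51.8 CPM against sets of 8.88 to 28.1), since cells with several hashtags hold them. Counts of U2AF1 and CCL3 can be shared with near-identical copies. KANSL1-AS1 lies in a region whose arrangement commonly varies between people and is an antisense gene, for which the use of strand in counting is not given in the sources used here.

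**Figure D2:**
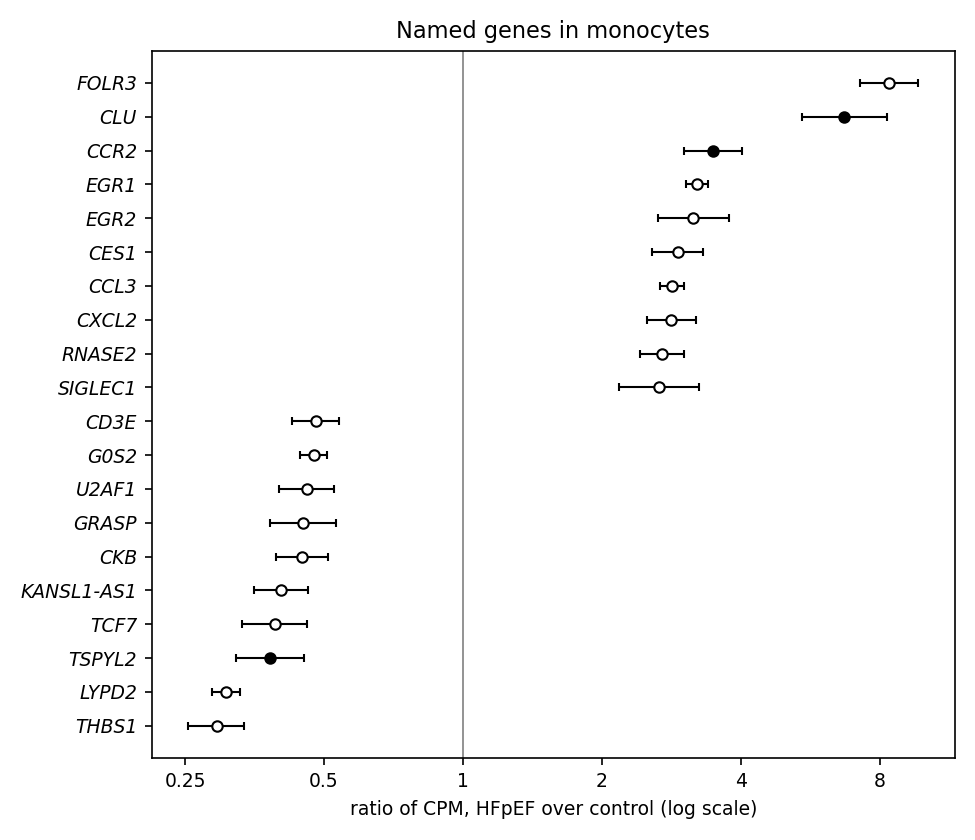
Ratio of CPM in monocytes, HFpEF over control (horizontal axis, log scale), for the 10 highest and 10 lowest genes by the fixed rule, with 95% counting intervals. Filled points mark genes whose hashtag sets had ranges apart (CLU, CCR2 and TSPYL2); FOLR3 had the highest ratio, 8.36, and THBS1 the lowest, 0.292.

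Among the gene lists fixed before the data were examined, the interferon response was higher in HFpEF in each of the 4 classes in which it was compared. The classes come from the same libraries and hashtag sets, so they are not separate observations. In monocytes the median log2 ratio of its 26 measured members was 0.53, above all 10000 random lists matched on expression, with 11 members at least 1.5-fold higher and 0 lower; IFI44L (2.46), IFI44 (1.94) and IFITM3 (1.82) had the highest ratios in the list. The list of alarmins and classical monocyte genes had a median of 0.44 over 15 members, also above all random lists, with 5 members higher and THBS1 lower. Its members CD163, a haemoglobin scavenger receptor (48.0 and 94.8 CPM, ratio 1.98), CLEC4E (1.96), MNDA (1.63) and RNASE6 (1.56) had hashtag ranges apart. S100A8 stood at 15175 and 21383 CPM. Fc receptors, complement and integrins had a median of 0.36 over 17 members, with 4 higher, among them C1QB (2.55) and FCGR1A (2.17), and 0 lower. FCGR1A encodes the high-affinity IgG receptor CD64 and had ranges apart (44.2 and 95.8 CPM), although its counts can be shared with the copy FCGR1B, and FCGR3A had a ratio of 0.760. Surface CD64 averaged 1.98 and 2.05 counts per monocyte, with overlapping ranges. As a share of all antibody counts its ratio was 1.21, against 1.40 to 2.14 for the isotype controls. Antibodies to other products of the list (CD11a, CD11b, CD11c, CD18, CD16, CD32 and CD35) had ratios from 0.654 to 0.919, and CD88 had 1.21.

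Inflammatory cytokines and NF-kB targets had a median of 0.31 over 18 members, above all random lists, with 6 members higher, among them CCL4 (5.71) and IL1B (1.96), and G0S2 lower. This rested on a classical monocyte cluster led by G0S2, IL1B, CXCL8 and CCL3 and on a single hashtag set: the median was −0.06 without that cluster and −0.12 without HFpEF Hashtag4. Immediate-early and AP-1 genes had a median of 0.13 (percentile 98.65), with 3 members higher and 1 lower, and of 0.00 without the cluster and −0.07 without HFpEF Hashtag4. Ribosomal protein genes had a median of −0.25 over 35 members, at percentile 0.01 of random lists, and mitochondrially encoded genes one of 0.15 (98.4), in a library whose kept cells had a median mitochondrial share of 4.18% against 3.42% in control. Lists within the central 95% of random lists were MHC class II presentation (median −0.13), heat shock (0.10), nuclear-encoded oxidative phosphorylation (0.07), glycolysis and hypoxia (−0.06), lipid handling and cholesterol (0.09), chemokine receptors (0.02, including CCR2, and −0.01 with TMM factors) and matrix and TGF-beta genes (−0.10). Without the cluster led by G0S2 the medians were 0.34 for lipid handling, −0.04 for chemokine receptors, 0.01 for matrix genes and 0.23 for Fc receptors, complement and integrins. Lymphocyte genes in monocytes went both ways, with a median of −0.17, GNLY at a ratio of 2.24 and CD3E at 0.480; the median was 0.08 without HFpEF Hashtag4 and 0.80 without cells that carried several hashtags. It was 0.06 as a mean of per-cell CPM and 0.08 with a lower minimum count. Granulocyte genes summed to 46.2 CPM in control and 53.6 in HFpEF, and platelet genes to 222 and 309 CPM. Most of the platelet sum was NRGN, at 198 and 223 CPM, beside 13.4 and 48.2 CPM of PPBP. Of the erythroid genes, 5 cells held 99.2% of the HFpEF UMIs in monocytes and 96.2 to 99.9% of those in the lymphocyte classes, so no ratio is given. Leaving out control Hashtag2 gave −0.05 for the chemokine receptors.

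**Figure D3:**
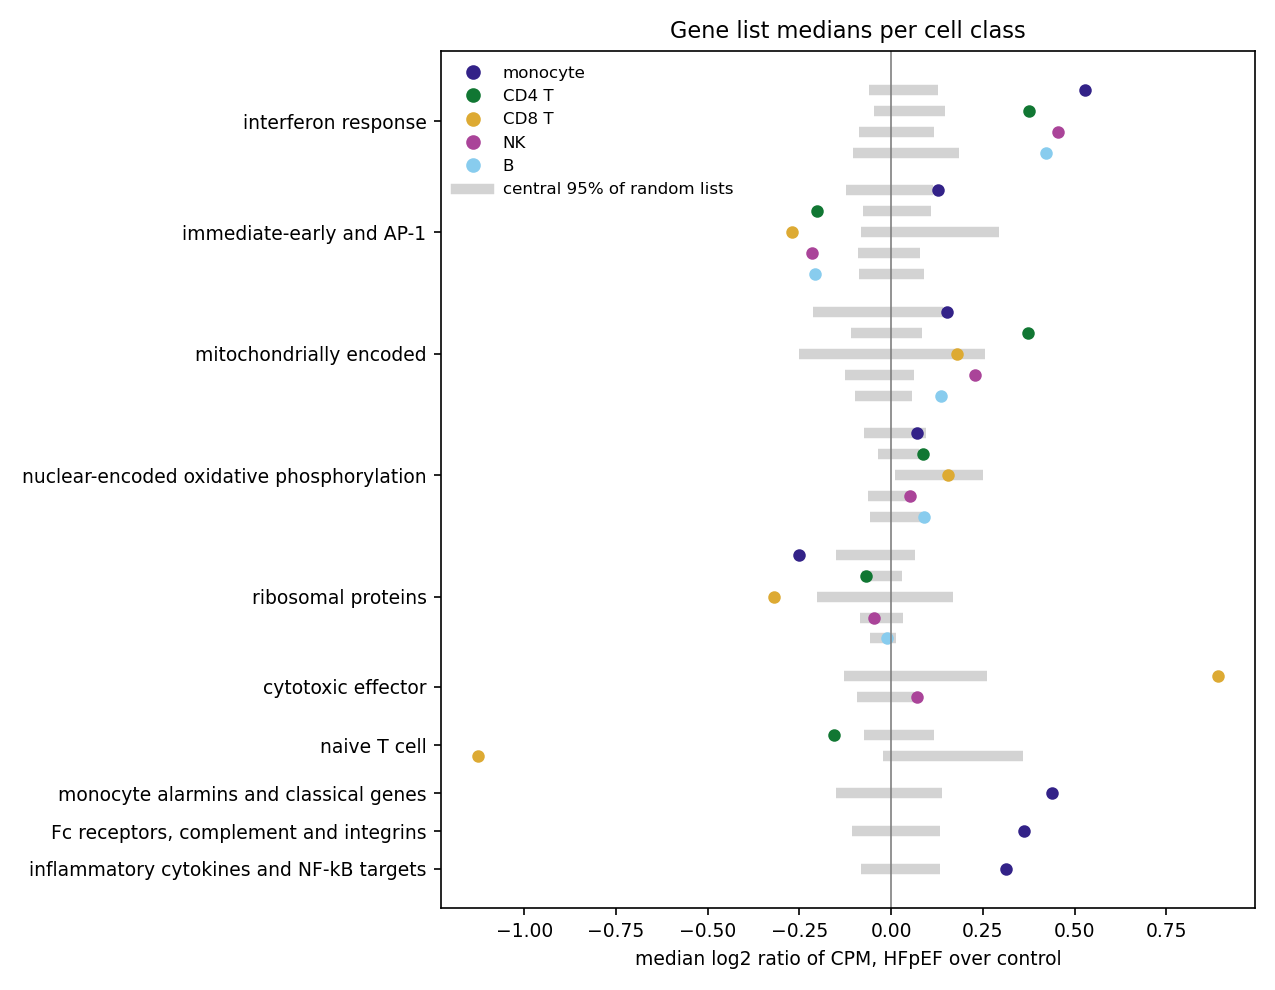
Median log2 ratio (HFpEF over control, horizontal axis) of 10 gene lists in each class where they were compared, with the central 95% of 10000 random lists of the same size and expression in grey. The interferon response lay above the grey range in monocytes (0.53), CD4 T (0.37), NK (0.45) and B cells (0.42).

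In CD4 T cells, interferon-response genes were higher and naive T cell genes lower in the HFpEF library, and few genes differed by much: of 4996 genes, 4 were at least 2-fold higher and 3 at least 2-fold lower. This count was 16 when called doublets were kept, 15 without HFpEF Hashtag5, and 11 without control Hashtag2, control Hashtag4 or HFpEF Hashtag2. With TMM factors the split was 4 higher and 5 lower. IFITM3, an interferon-induced membrane protein that restricts virus entry, stood at 7.75 and 25.4 CPM, a ratio of 3.28 (2.70 to 4.0), with control sets from 2.36 to 11.7 and HFpEF sets from 14.3 to 28.0 CPM. PRF1, which encodes perforin, had a ratio of 1.84 (13.7 and 25.2 CPM), also with ranges apart. The other genes highest by the rule, none with ranges apart, were KLRG1 (2.31), TNFAIP8L2 (2.29), GZMA (1.996), HOPX (1.998), ISG15 (1.79), LGALS3 (1.81), C14orf119 (1.82) and GZMK (1.61). Lowest were KRT1 (0.333), GADD45B (182 and 90.0 CPM, 0.494), NELL2 (0.496), SNHG5 (0.542), CRIP2 (0.517), CENPK (0.547), SERTAD1 (0.541), H2AFX (0.545, with ranges apart), NOG (0.535) and SMDT1 (0.632). KRT1 had a log2 ratio of −1.59, −0.89 without control Hashtag3 and −2.90 without HFpEF Hashtag1.

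The interferon list had a median of 0.37 over 18 members in CD4 T cells, above all random lists, with 5 higher and 0 lower. Genes of naive T cells had a median of −0.16 over 14 members (percentile 0.01), with NELL2 at least 1.5-fold lower and 0 members higher, and the cluster led by naive T cell genes was 42.6% of control and 38.5% of HFpEF CD4 T cells. Immediate-early genes had a median of −0.20, below all random lists, with no member 1.5-fold apart, and one of 0.02 when called doublets were kept. Heat shock genes had a median of 0.24 (99.98) and 0 members 1.5-fold higher, while DNAJB1, a co-chaperone of HSP70, had a ratio of 0.651 with ranges apart. Mitochondrially encoded genes had a median of 0.37 (above all random lists) and nuclear-encoded oxidative phosphorylation genes 0.09 (99.1). T cell activation (0.17), T helper and regulatory genes (0.14), glycolysis (−0.00), chemokine receptors (0.01, and −0.07 with TMM factors) and ribosomal proteins (−0.07) lay within the central 95%, and the medians for glycolysis and chemokine receptors changed sign without some sets (−0.01 for the receptors without control Hashtag2, 0.03 for glycolysis without control Hashtag4). Within activation and regulatory genes, TIGIT had a ratio of 1.71 and FOXP3 of 1.62, and the cluster led by FOXP3 was 10.8% of control and 14.3% of HFpEF CD4 T cells. Monocyte genes summed to 71.3 and 96.8 CPM in these cells, platelet genes to 6.91 and 27.2 CPM, and cell cycle genes to 33.8 and 37.8 CPM.

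In CD8 T cells, genes of cytotoxic effector cells were higher and genes of naive cells lower in the HFpEF library. Of 5653 genes, 90 were at least 2-fold higher and 49 at least 2-fold lower, and without control Hashtag3 the count of both was 241. Hashtag ranges were apart for 3 of the higher and 0 of the lower genes. HFpEF Hashtag1 and Hashtag2 held 757 and 788 CD8 T cells, against 56 to 361 in the other HFpEF sets. The makeup of the class differed: the naive-like cluster was 42.2% of control and 11.9% of HFpEF CD8 T cells, and the effector cluster 57.8% and 88.1%. Within the effector cluster alone, 37 genes were higher and 24 lower, 43 of them among those counted in the whole class. Scaling mattered here, since TMM factors shifted the log2 ratios by −0.13 (median-of-ratios factors also by −0.13) and gave 64 higher and 69 lower, and median-of-ratios factors 67 and 69.

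The cytotoxic list had a median of 0.89 over 19 members, with 15 higher and 0 lower, among them KLRD1 (CD94), GNLY (2.48), CX3CR1 (2.61) and IFNG. The naive T cell list had a median of −1.13 over 13 members, with 12 lower, among them CCR7 (0.374), LEF1 (0.431) and TCF7 (0.458), and 0 higher. Within the effector cluster alone these medians were 0.18 and −0.35. By the rule, the highest genes were FGL2 (4.85 and 33.4 CPM, ratio 6.88, interval 4.68 to 10.5), IFNG (9.87 and 45.8 CPM, 4.64), KLRD1 (137 and 519 CPM, 3.78), KLRC2 (3.40) and ZNF683 (3.38), and the lowest NELL2 (110 and 26.8 CPM, 0.245), BACH2 (0.261), TRABD2A (0.304), ARMH1 (0.326) and TMIGD2 (0.292). The hashtag ranges of all these genes overlapped. Within the effector cluster their log2 ratios were 2.25 for FGL2, 1.47 for IFNG, 1.201 for KLRD1, 1.08 for KLRC2, 1.25 for ZNF683, −1.80 for NELL2, −0.72 for BACH2, −0.62 for TRABD2A, −1.02 for ARMH1 and −1.09 for TMIGD2. Without HFpEF Hashtag1 the log2 ratio of FGL2 was 2.20 (2.78 with it), and without HFpEF Hashtag2 that of KLRC2, a gene with close copies and a common deletion, was 0.77 (1.76). Immediate-early genes had a median of −0.27, below all random lists, with JUN (0.639), JUNB (0.588) and BTG2 lower and KLF6 higher, and ribosomal proteins one of −0.32 (percentile 0.03). Activation (0.23), chemokine receptors (0.35), oxidative phosphorylation (0.16), mitochondrially encoded genes (0.18) and monocyte genes (0.40) lay within the central 95%. Within the effector cluster alone the medians were −0.10 for activation, 0.11 for chemokine receptors, 0.08 for oxidative phosphorylation, 0.07 for mitochondrially encoded genes, 0.12 for monocyte genes, −0.10 for ribosomal proteins and −0.47 for immediate-early genes. Cell cycle genes summed to 36.5 and 52.8 CPM and platelet genes to 10.4 and 36.6 CPM.

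In NK cells, IFNG, the cytokine interferon-gamma, and genes it or other interferons induce were higher in the HFpEF library, and immediate-early genes were lower. Of 5475 genes, 13 were at least 2-fold higher and 7 at least 2-fold lower, and the count of both was 119 with called doublets kept and 6 with cells thinned to equal depth. All 5 genes highest by the rule had hashtag ranges apart: IFNG (12 and 38.5 CPM, ratio 3.21, interval 2.36 to 4.41), PALM2-AKAP2 (2.77), GBP1 (24.4 and 59.9 CPM, 2.46), TRG-AS1 (2.48) and LGALS3 (27 and 61.2 CPM, 2.26). GBP1 is an interferon-induced guanylate-binding protein and LGALS3 encodes galectin-3. IFNG (ENSG00000111537) lies on chromosome 12 from 68154768 to 68159747. Lowest were DUSP2 (250 and 120 CPM, 0.480), SPOCK2 (0.475), PECAM1 (0.479), NEIL1 (0.455) and CD8A (0.537), and their ranges overlapped. CD8A had a log2 ratio of 0.28 when called doublets were kept. TRG-AS1 is antisense, with the same limit on strand.

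The interferon list had a median of 0.45 over 18 members in NK cells, above all random lists, with 6 higher and 0 lower, among them IFI6 (1.74) and EPSTI1 (1.72). Immediate-early genes had a median of −0.22, below all random lists, with DUSP2, JUNB (0.628) and NR4A2 (0.634) lower, and one of 0.14 when called doublets were kept. The cytotoxic list had a median of 0.07 (98.3) over 20 members, with IFNG and FASLG (1.56) higher, of −0.00 without HFpEF Hashtag4 and of −0.12 with doublets kept. Mitochondrially encoded genes had a median of 0.23, above all random lists, while oxidative phosphorylation (0.05) and ribosomal protein genes (−0.05) lay within the central 95%. Monocyte genes had a median of −0.26 (1.79) over 3 members, and of 1.24 with doublets kept. In these cells platelet genes summed to 12.4 and 33.1 CPM and cell cycle genes to 74.0 and 85.2 CPM.

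In B cells, interferon-response genes and the lysosomal thiol reductase IFI30 were higher in the HFpEF library, and immediate-early genes were lower, which rested on the control Hashtag2 set. Of 4007 genes, 17 were at least 2-fold higher and 15 at least 2-fold lower. TMM factors gave 14 and 19, and median-of-ratios factors, which shifted the log2 ratios by −0.11, gave 13 and 22. IFI30 stood at 130 and 248 CPM, a ratio of 1.90 (1.70 to 2.13), with ranges apart. Monocyte genes were also higher in HFpEF B cells (below), and their part in the IFI30 ratio was not tested. The other highest genes were STAG3 (45.9 and 142.2 CPM, 3.10), SESN1 (2.80), the antisense gene GABPB1-AS1 (2.12) and ID3 (2.06). Lowest were PELI1 (127 and 47.3 CPM, 0.374), GADD45B (0.395), SNX9 (0.429), PMAIP1 (0.437) and CD83 (248 and 130 CPM, 0.524), a surface marker of activation. Ranges overlapped for all of these named genes but IFI30. STAG3 had a log2 ratio of 1.63, and 2.26 without control Hashtag5. Without control Hashtag2 the log2 ratio was −0.71 for PELI1 (−1.42 with it), −0.61 for SNX9 (−1.22), −0.53 for PMAIP1 (−1.19) and −0.29 for CD83 (−0.93).

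The interferon list had a median of 0.42 over 15 members in B cells, above all random lists, with 4 higher, among them MX1 (1.81) and OAS1 (1.74), and 0 lower. Immediate-early genes had a median of −0.21 (percentile 0.01), with JUNB (0.566), NR4A2 (0.463) and RHOB (0.605) lower, and one of −0.01 without control Hashtag2. Mitochondrially encoded genes had a median of 0.14 and oxidative phosphorylation genes one of 0.09 (98.2), both above the central 95%, and the latter became negative under the median-of-ratios shift of −0.11, which moves all genes alike and so leaves its place among random lists. MHC class II presentation (0.01, and −0.07 with TMM factors), memory and activation genes (−0.10) and ribosomal proteins (−0.01) lay within it, and each changed sign without control Hashtag2 (−0.03, 0.01 and 0.01). Monocyte genes stood out, with a median of 1.66 over 3 members, S100A8 at 55.9 and 211 CPM (sets 18.5 to 72.6 and 15.8 to 114 CPM, with more in cells of several hashtags), and platelet genes summed to 87.3 and 120 CPM.

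The antibody counts were compared as shares of all antibody counts of a class, hashtags included. The isotype controls, which bind no specific target, had more counts per cell in HFpEF in every class, with ratios of 1.46 in monocytes, 1.37 in CD4 T, 1.35 in CD8 T, 1.36 in NK and 1.21 in B cells, and hashtag counts per monocyte were 830 in control and 548 in HFpEF. On this scale 50 antibodies were at least 1.5-fold higher and 2 lower in monocytes, 7 and 1 in CD4 T, 5 and 5 in CD8 T, 3 and 4 in NK, and 45 and 0 in B cells. With hashtags left out of the total these became 10 and 15, 3 and 10, 3 and 11, 3 and 4, and 6 and 7, so the counts in both directions depend on the scale. Centred log ratios per cell gave 3 and 10 in monocytes, 2 and 2 in CD4 T and 2 and 4 in B cells. Leaving out control Hashtag2 took the count from 45 to 9 in B cells and from 52 to 28 in monocytes. Leaving out control Hashtag5 took it from 8 to 25 in CD4 T and from 10 to 21 in CD8 T cells, and leaving out control Hashtag4 took it to 23 in CD4 T cells.

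CD62P and CD49b had the highest ratios in all 5 classes among antibodies other than isotype controls. CD62P (P-selectin), which activated platelets display, averaged 4.93 counts per control monocyte and 13.3 per HFpEF monocyte, a ratio of shares of 3.17, and the ratio was 4.08 in CD4 T, 4.24 in CD8 T, 3.79 in NK and 5.04 in B cells. CD49b, a collagen receptor chain found on platelets and on some lymphocytes, had ratios of 2.65, 2.77, 2.99, 2.51 and 3.22 in the same order. CD41 had ratios of 1.34 in monocytes (below each of the 7 isotype controls on this scale), 2.38 in CD4 T, 2.22 in CD8 T, 2.20 in NK and 2.51 in B cells, and CD42b one of 2.29 in monocytes. Counts per cell had hashtag ranges apart for CD62P, CD49b and CD41 in all 4 lymphocyte classes but not in monocytes. For CD42b, compared in monocytes only, they were apart. The lowest ratios in monocytes were CD33 (5.23 and 2.11 counts per cell, 0.472), CD11a (0.654) and CD18 (0.685), all with ranges apart. Ranges apart were common for antibodies, at 79 of 122 in monocytes and 80 of 113 in CD4 T cells. They were found for 67 of 113 in CD8 T, 76 of 112 in NK and 35 of 117 in B cells. Lowest in CD4 T cells were CD27 (0.643), CD99 (0.677) and CD5 (0.691), and in CD8 T cells CD27 (0.398), CD62L (0.428) and CD8 (0.583); CD27 and CD62L mark naive and central memory cells. In NK cells CD328 (0.551), CD45RA (29 and 19.5 counts per cell, 0.611) and CD16 (0.619) were lowest, with ranges apart, and in B cells IgM (0.673), CD5 (0.679) and CD21 (0.776).

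A few genes differed in the same direction in several classes. These were chosen after their values were seen. FKBP5, a co-chaperone that limits glucocorticoid receptor activity and is itself induced by it, had a ratio of 1.94 in monocytes (54.6 and 106 CPM, interval 1.79 to 2.11), 1.48 in CD4 T, 1.32 in CD8 T, 1.80 in NK and 2.82 in B cells, where it was below the minimum count. Its hashtag ranges were apart in all 5 classes. It lies on chromosome 6 from 35573585 to 35728583 (ENSG00000096060). DNAJB1 was lower in all 5, with ratios of 0.668, 0.651, 0.576, 0.602 and 0.670 in the same order and ranges apart in CD4 T, NK and B cells. PPBP stood at 13.4 and 48.2 CPM in monocytes, 2.01 and 9.92 in CD4 T, 3.68 and 15 in CD8 T, 5.08 and 15.6 in NK, and 18.1 and 43.4 in B cells, with ranges apart in all but NK cells. CLU, in contrast, had ratios of 1.28 in CD4 T (interval 0.941 to 1.74) and 1.17 in NK cells (0.524 to 2.60), where no difference was detectable at this depth, and 1.66 in CD8 T cells (1.13 to 2.49), with overlapping ranges.

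**Figure D4:**
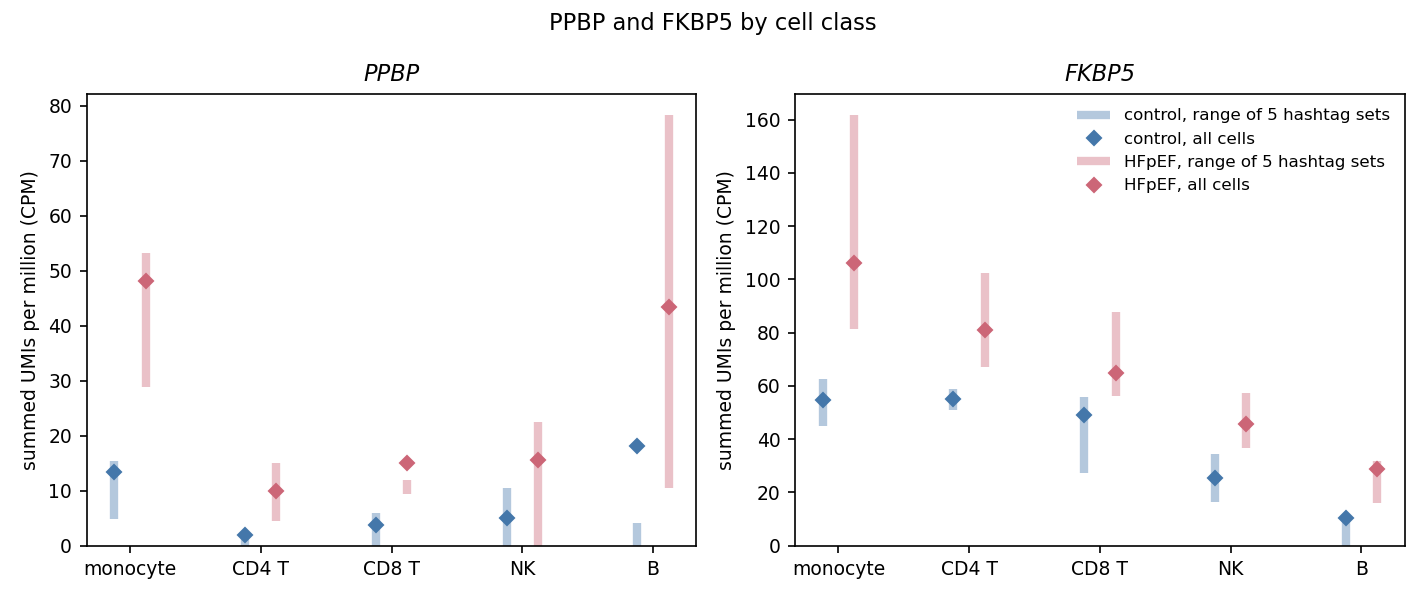
PPBP and FKBP5 in each class (CPM, vertical axis) of the control and the HFpEF library; diamonds show all cells and bars the range of the 5 hashtag sets, whose cells carry 1 hashtag. FKBP5 stood at 54.6 CPM in control and 106 CPM in HFpEF monocytes.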

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

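All tests in this part were chosen after the pattern they address was seen. The lists of glucocorticoid genes and of NF-kB genes in B cells were also added after the data were seen. Only the predictions for these lists were written before their tests were run. Among 22 groups of 5 hashtag sets, 2 held a set far from the other 4, where chance gives about 1 in 20 groups. Conventional dendritic-like cells were 3.77% of the control Hashtag2 set, against 2.18% in the next highest and 1.62% in the lowest set. A cluster of classical monocytes led by G0S2, IL1B and CCL3 was 37.3% of the HFpEF Hashtag4 set, against 9.80% in the next highest and 0.431% in the lowest.

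In control, the same inflammatory monocyte cluster was also most frequent in 1 set, with 26.3% of Hashtag2 and at most 9.59% of the others. It was 73.2% of the monocytes of control Hashtag2 and 36.1% of those of control Hashtag4. Cells with several hashtags were 1.12 times as frequent in the cluster as in the other classical clusters pooled (23.5%, against 22.0% and 18.3% in each). This argues against joined sets as its main source but leaves joined cells of 1 set open. Its mitochondrial share was 0.959 times theirs. That cannot decide on dying cells, since cells at or above 10% mitochondrial UMIs had been removed. An exposure or handling of the whole set could raise NF-kB genes in its other cells too. In B cells these genes ranked 1 of 5 in the control set (2230 CPM). They ranked 2 of 5 in the HFpEF set (1999 CPM, against 2082 CPM in Hashtag5). HFpEF Hashtag5 was itself next highest for the cluster, at 29.8% of its monocytes against 63.7% in HFpEF Hashtag4. Control Hashtag4, next highest in control, ranked 3 of 5 in B cells (1273 CPM). Handling and exposure therefore stay open and cannot be told apart. What the sets are is not given in the sources used here, so no biological explanation was tested.

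Cells with platelet and monocyte RNA were the class whose hashtag ranges lay apart. Among cells called with 1 hashtag they were 0.242% of control and 1.10% of HFpEF cells, a ratio of 4.54 (counting interval 3.12 to 6.77). Over all cells the ratio was also 4.54. This cannot decide on joined droplets, since joins within 1 set would rise along with joins between sets. More than 1 hashtag was called in 56.7% of mixed cells, against 19.2% of all kept control and 20.1% of HFpEF cells. Joined droplets stay open. Loose platelets could raise platelet-like and mixed cells. The fold of mixed cells was 3.10 times that of platelet-like cells (2.18 to 4.42, counting error only), but this cannot decide on loose platelets. Platelet-like droplets had to reach the minimum UMIs alone, and those kept had medians of 1041 UMIs in control and 1119 in HFpEF. Loose platelets below the minimum were therefore not counted. Platelet-like shares also varied between sets, from 0.229 to 1.06% in control and from 0.0499 to 1.76% in HFpEF. Loose platelets stay open. Free platelet RNA brings no surface protein. Mixed cells had 2.60 to 10.4 times the CD41 counts of monocytes of the same set in all 10 sets, which argues against such RNA. It stays open for the remaining monocytes, whose platelet UMIs per cell differed by 1.54 times as much as those of CD4 T cells (1.12 to 2.03). Monocytes held NRGN of this list at 198 and 223 CPM, beside 13.4 and 48.2 CPM of PPBP, which blurs that comparison. Platelets bound to monocytes in HFpEF blood, or bound during handling, may also give this pattern; neither was tested.

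FKBP5 was higher in HFpEF in all 5 classes. Within the largest classical monocyte cluster alone its ratio was 2.12 (1.88 to 2.39), which argues against a different mix of monocyte clusters. A broad glucocorticoid response would raise other genes of that response, but their list lay above the central 95% of random lists in 0 of 5 classes, with medians of 0.08 in monocytes, −0.19 in CD4 T, −0.20 in CD8 T, −0.07 in NK and −0.12 in B cells; in CD4 T and CD8 T cells the list lay below the central 95% (percentiles 0.02 and 0.07). Cell makeup also bears on the CD8 T median: PIK3IP1 of that list, also a naive T cell gene, had a ratio of 0.512 there. The naive-like cluster was 42.2% of control and 11.9% of HFpEF CD8 T cells. A response limited to FKBP5 or to genes outside that list, a variant of the donors and the condition itself stay open as untested explanations.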

How the results depend on the processing

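Alternatives that remove or combine hashtag sets, take single clusters or leave hashtags out of the antibody total were chosen after the data were seen. No paired analysis was possible because each group was 1 sample, and no result comes from a test. Leaving-out apart, 599 of 660 values of named genes kept their direction and stayed within their counting spread, and with sets left out 595 of 700 did. The former count includes the lower minimum count and the absence of a filter, which change only which genes enter. Values of named genes could not move under these, so that count overstates their stability. For list medians, 283 of 319 and 471 of 500 were counted as unchanged, with a limit set by the range of random lists. That count does not require the same sign. The median of MHC class II presentation in B cells, for example, went from 0.01 to −0.03 without control Hashtag2. Of the class differences in share, 48 of 77 moved by less than their counting interval, as did 57 of 90 with sets left out. Gene counts stayed within 1.5 times in 30 of 47 and antibody counts in 14 of 20 alternatives. Unless stated, the cause was not tested.

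Differences in share (HFpEF minus control, in percentage points) were as follows. Antibody gates, which held a smaller part of each class in HFpEF, gave −2.66 for B, −5.76 for CD4 T, 0.095 for CD8 T, −0.616 for NK, 3.15 for classical and −0.235 for nonclassical monocytes. Keeping called doublets gave −14.1 for CD4 T, 5.44 for CD8 T, −0.149 for NK, 7.40 for classical monocytes and 2.06 for mixed platelet and monocyte cells. The stricter filter gave 8.34 for CD8 T, 8.40 for classical and −0.402 for nonclassical monocytes, 1.08 for mixed and 0.442 for plasmacytoid dendritic cells, and the looser filter 1.30 for nonclassical monocytes. Clustering each library on its own gave −16.7 for CD4 T, 7.53 for CD8 T and 0.705 for mixed cells, which were 0.870 without cells of several hashtags. Medians over the sets gave 0.873 for B, −18.2 for CD4 T, −1.19 for CD8 T (reversed), −4.12 for NK, 3.45 for classical and −1.19 for nonclassical monocytes, −0.744 for conventional dendritic and 0.962 for mixed cells. Leaving out sets in turn gave −0.932 to 0.390 for B, −17.9 to −13.1 for CD4 T, 3.95 to 8.24 for CD8 T, −3.57 to −0.532 for NK, 5.43 to 11.8 for classical and −0.696 to 0.905 for nonclassical monocytes, and −0.024 to 0.361 for plasmacytoid dendritic cells.

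Counts of genes at least 2-fold apart grew where more genes with few UMIs entered. The lower minimum of 50 UMIs gave 281 in monocytes, 147 in CD4 T, 436 in CD8 T, 97 in NK and 170 in B cells, and no filter 2284, 1557, 2218, 1534 and 1835. Thinning, which lets fewer genes enter, gave 65 in CD8 T, 6 in NK and 10 in B cells. Keeping doublets gave 16 in CD4 T and 119 in NK cells, per-cell CPM 11 in CD4 T cells, and the effector cluster alone 61 in CD8 T cells. Leaving out sets gave 6 to 15 in CD4 T and 103 to 241 in CD8 T cells. Antibody counts were 13 in monocytes, 4 in CD4 T and 6 in B cells with centred log ratios, and 25, 13 and 13 with hashtags left out of the total. Leaving out sets gave 28 to 57 in monocytes, 7 to 25 in CD4 T, 10 to 21 in CD8 T and 9 to 58 in B cells.

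Lists outside the central 95% were 8 of 15 in monocytes, 6 of 11 in CD4 T, 4 of 9 in CD8 T, 5 of 7 in NK and 5 of 8 in B cells. They were 10 in CD4 T cells at 50 UMIs, 3 in B cells with the stricter filter or doublets kept, and 4 to 7 in CD8 T and 2 to 6 in NK cells with sets left out. With doublets kept the log2 values turned to 0.28 for CD8A in NK cells, −0.12 for the cytotoxic list in NK cells, 0.021 and 0.14 for immediate-early genes in CD4 T and NK cells and 1.24 for monocyte genes in NK cells. Lymphocyte genes in monocytes turned to 0.80 without cells of several hashtags, 0.058 with per-cell CPM and 0.077 at 50 UMIs, and the inflammatory list in monocytes to −0.058 without the cluster led by G0S2. Leaving out sets gave −0.0031 to 0.074 for the cytotoxic list in NK cells, and in monocytes −0.074 to 0.18 for immediate-early, −0.12 to 0.50 for inflammatory and −0.41 to 0.079 for lymphocyte genes.

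Alternatives that leave out parts of a library by barcode suffix were not run, since all barcodes share 1 suffix. Resolution 0.5 gave no mixed platelet and monocyte class, and gates gave no dendritic or mixed cells. With the depth of B cells, 82 of 100 simulated 2.5-fold differences were found, against 97 in monocytes, so fewer differences can be seen in the smaller classes.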

Other observations

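All genes in this part were chosen after their values were seen, and none was tested. Further genes at least 1.5-fold apart with hashtag ranges apart add to the monocyte profile. FCGR1B, the copy of the CD64 gene, had a ratio of 2.13 in HFpEF monocytes, FAM20A one of 2.33 and RAB13 one of 2.02. DUSP6, a phosphatase that limits ERK signalling, had a ratio of 1.58, and the tetraspanin CD63 one of 1.52.

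Some single genes of lymphocytes had ranges apart as well. HLA-DMA, which loads peptides onto MHC class II, stood at 27.1 and 50.6 CPM in CD8 T cells, a ratio of 1.87, and IFI35 had a ratio of 1.76 there. In NK cells DTX3L (32.5 and 61.7 CPM, 1.90) and PLSCR1 (1.73), both induced by interferon, were higher in HFpEF. In B cells the cysteine protease CTSB (1.62) and the protease inhibitor CSTB (100 and 174 CPM, 1.73) were higher, and the RNA-binding protein RBM38 lower (180 and 100 CPM, 0.557). Monocytes hold more of CTSB and CSTB (268 and 459 CPM in control), and monocyte genes were higher in HFpEF B cells too, with S100A8 at 55.9 and 211 CPM. Counting genes with ranges apart in the same direction in 3 or more classes gave 3 (FKBP5, DNAJB1 and a haemoglobin gene held by few cells), while 1000 draws that treat the classes as independent gave at most 1; the classes share their hashtag sets, so this is a weak comparison.

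In mixed platelet and monocyte cells CD62P averaged 35.0 counts per cell in control and 101 in HFpEF, CD42b 5.84 and 16.6, and CD14 4.01 and 4.04. In mixed cells with 1 hashtag the means were 26.3 and 46.8 for CD62P and 4.09 and 8.24 for CD42b, and the medians 18 and 19, and 3 and 3. In all mixed platelet and monocyte cells CLU stood at 535 and 415 CPM and PPBP at 2874 and 2290 CPM. NF-kB genes chosen for B cells had list medians of 0.07 in monocytes, −0.10 in CD4 T, −0.30 in CD8 T, −0.29 in NK and −0.20 in B cells, below the central 95% of random lists in all but monocytes, although members went both ways in CD8 T and NK cells. Summed in B cells, these genes stood at 2230 CPM in control Hashtag2, against 1081 to 1561 CPM in the other control sets. HFpEF sets ran from 891 to 2082 CPM.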
